A study of Mus musculus with 9 samples.

How the data were processed

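RNA-seq libraries of sorted wild-type mouse CD8+ T cells kept for 24 h in 3 media were used, 3 libraries per medium and 9 in all. Per the labels, the cells had about 80% live cells before sorting, the medium held 10% dialyzed FBS, all libraries belong to 1 batch, and sequencing was paired-end on an Illumina instrument. The labels do not state the strand of the libraries. Per the submitters' processing notes, HISAT2, featureCounts, Subread 2.0.1 and DESeq2 1.38.3 were used with the mm10 genome, and the notes do not give the part each tool played. The deposited tables hold FPKM per gene and library, fragments scaled by gene length and library size as the authors computed them. They also hold, as deposited, a group mean signal per gene that behaves as a size-factor-normalized read count averaged over 3 libraries. The log2 fold changes in the deposited tables were computed by the authors, and in the 2 tables with hypoxanthine they are given as control minus hypoxanthine. The p-values and adjusted p-values in the same tables were made by the authors, and their column of significant genes is TRUE where the unadjusted p is under 0.05 and the log2 fold change is over 1 in size, which holds for all 20618 genes of each table.

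The test was limma 3.58.1 in R 4.3.3, with trend and robust settings, on log2(FPKM + 1) of all 20618 genes and 9 libraries in 1 fit with a mean per medium (6 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum and no filter. The 3 comparisons, the test among the 3 media, the 43 gene lists, the rule for named genes and most of the other settings tried were chosen before the data were examined. A count model had been set out for tables of counts and this limma test for normalized values, and the tables hold FPKM. The list tests, first set out for log2 CPM, were run on log2(FPKM + 1). Lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 43 lists, and again with a correlation estimated for each list and with fry. Every adjusted p in the text is from limma, camera or fry, and p-values measure the spread between these libraries. "Adjusted over the list alone" means the adjustment was made over that list's genes only.

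Whole reads per gene and library were recovered by solving the authors' 2 deposited group means of each medium for whole numbers, within 0.0005 of a whole number and at most 0.05, and, where several solutions remained, within 0.1 of the FPKM ratios on the log2 scale. This gave 20603 genes in all 9 libraries (99.93% of genes and 95.89% of FPKM). For 5290 genes with over 1000 reads in each library, the median SD of the log2 ratio of FPKM to recovered reads was 0.003. The 15 genes not recovered include Gzmb, COX1, Cfl1 and Eef1a1. Recovered reads were used for depth, the CPM rules, a read filter, limma voom (with library totals and no other scaling factor), thinning to equal depth and the comparison of libraries, and all other values rest on FPKM. Depth ran from 29735788 to 48202069 recovered reads, and 16245 to 17217 genes were above 0. Over the genes with a mean of at least 1 FPKM, the median SD within a medium on the log2 scale was 0.094 in glucose, 0.13 in inosine and 0.087 with hypoxanthine.

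Genes named in the text are 14 fixed genes, and for each comparison the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM, no overlap between the libraries of the 2 media and a symbol that is not a predicted gene, a pseudogene or a receptor segment. They also include up to 4 members of each list described, the 2 with the smallest adjusted p and the 2 with the highest mean CPM, and the 3 most significant genes in each direction of the test among the 3 media. For genes whose reads were not recovered, such as Gzmb and COX1, FPKM stood in for CPM in these rules. Genes named otherwise are said to be chosen after their values were seen. Coordinates are those of GRCm38.p6, the assembly also called mm10.

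The covariance between 2 comparisons that share libraries was set against 1000 simulations of unchanged groups, made by random rotation of the deviations from each medium's mean, all genes together. Shared calls and shared signs were set against 50 other simulations of unchanged groups. These drew normal noise for each gene on its own, which leaves out the correlation between genes. The tests were run first on simulated data of 20603 genes with 200 genes changed, 50 at each of 4 sizes. For 1.25, 1.5, 2 and 4 times, limma recovered 0, 19, 41 and 48 of 50 in the comparison of inosine with glucose, 0, 7, 39 and 48 with hypoxanthine against inosine, and 0, 13, 34 and 49 with hypoxanthine against glucose. False calls were 11 beside 108 true calls, 4 beside 94 and 6 beside 96. With no gene changed, false calls were 0, 1 and 1. The test among the 3 media recovered 165 of 200 with 15 false calls, so false calls were above the nominal rate of 5% in this test and in both comparisons with glucose, and the recovery of reads returned 3000 of 3000 simulated counts. Alternatives covered scaling, pseudocount, filters, limma voom, a replicate block, mitochondrial genes, a fold minimum, the 6 libraries compared and each library left out. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.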

Results

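RNA was sequenced from wild-type mouse CD8+ T cells, the cytotoxic lymphocytes of the adaptive immune system, after 24 h in 1 of 3 media. The first medium held 2 mM glucose, the second held 2 mM inosine, and the third held 2 mM inosine together with hypoxanthine. Inosine is a purine nucleoside made of the base hypoxanthine and a ribose sugar, and purine nucleoside phosphorylase (Pnp) splits it into the free base and ribose 1-phosphate. The hypoxanthine dose is printed in the labels as 100 M, from which a unit prefix has evidently been lost, so its molar amount is left open here. Each medium was represented by 3 libraries of sorted live cells, and the 9 libraries gave FPKM for 20618 genes. Recovered reads per library ranged from 29735788 in glucose replicate 1 to 48202069 in glucose replicate 3. With inosine they ranged from 34296694 to 40612640, and with hypoxanthine from 33735432 to 43152951. Nothing in the labels states that the 3 libraries of a medium came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. Over the 9947 genes with a mean of at least 1 FPKM, the first principal component held 68.6% of the variance. It placed the 3 libraries with hypoxanthine between 25.6 and 27.8 and the other 6 between -15 and -11.9. The second component held 15.3% and ran from -19.9 in inosine replicate 2 to 11.1 in inosine replicate 1.

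The comparison of inosine with glucose asks how the transcriptome of these cells differs when the nucleoside replaces the sugar. Cells in the 2 media expressed the main T cell genes at close levels. Gzmb, which encodes the cytotoxic protease granzyme B, stood at 5549 ± 127 FPKM in glucose and 5610 ± 88 FPKM in inosine (SD, n = 3). The pore-forming perforin gene Prf1 stood at 184 ± 37.2 and 186 ± 49.2 FPKM, and the interferon gamma gene Ifng at 184 ± 76 and 205 ± 48.5 FPKM (SD, n = 3). The glycolytic genes Eno1 and Gapdh differed by 0.17 ± 0.09 and 0.18 ± 0.11 on the log2 scale (standard error), each with a limma adjusted p of 1. The same adjusted p was obtained for each of the 14 genes fixed for all comparisons. Among them, Pnp had a log2 difference of 0.14 ± 0.09, the salvage enzyme gene Hprt 0.08 ± 0.09, the glucose transporter gene Slc2a1 -0.08 ± 0.21, the thioredoxin-interacting protein gene Txnip 0.06 ± 0.41 and the arginine methyltransferase gene Carm1 -0.18 ± 0.16 (standard error). Of 20618 genes, limma called 2, and 584 had an unadjusted p under 0.05 where 1031 would be given by chance. A count below chance can arise when the error is too wide, as it would be if libraries of equal replicate number shared variation. Small differences can then be missed. With a replicate block in the fit of all libraries 1 gene was called. That block gives all 3 media a common effect per replicate number, so it need not remove variation shared by glucose and inosine alone. A paired fit of only the glucose and inosine libraries was not run. limma voom on the recovered reads called 0. The 2 called genes, named here after their values were seen, were the predicted genes Gm38782 (0.062 ± 0.011 FPKM in inosine, listed at 0 in glucose) and Gm41667 (0.095 ± 0.0093 FPKM in glucose, listed at 0 in inosine; SD, n = 3). No gene met the rule for the largest changes. Among the members picked from lists, the oxidative phosphorylation gene Atp5d stood at 222 ± 41.6 FPKM in glucose and 127 ± 26.8 FPKM in inosine (SD, n = 3). Its log2 difference was -0.8 ± 0.2 (standard error). It did not pass, although the libraries of the 2 media did not overlap. For genes with a mean of at least 1 FPKM, 99.6% had a 95% interval of the log2 difference inside -1 to 1. This is on the log2(FPKM + 1) scale, which understates the change of low genes.

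Among the 43 gene lists, only the list of the 13 genes encoded by mitochondrial DNA passed camera in the comparison of inosine with glucose, upward (adjusted p = 0.00167). It did not pass with an estimated correlation (adjusted p = 0.999), and none of its 13 members rose or fell, also when adjusted over the list alone. COX1 stood at 4218 ± 303 FPKM in glucose and 5638 ± 1540 FPKM in inosine, and ND1 at 2073 ± 182 and 2596 ± 716 FPKM (SD, n = 3). Mitochondrial genes took 6.5% of the FPKM in inosine replicate 2 and 5.84% in replicate 2 with hypoxanthine, against 4.03 to 4.82% in the other 7 libraries. Without inosine replicate 2 the list had an adjusted p of 0.4, and without glucose replicate 2 one of 0.12. The count of lists that passed went to 7 without glucose replicate 1, 3 without glucose replicate 2, and 8 without inosine replicate 1 or replicate 2. The interferon list was among them, downward without glucose replicate 1 (adjusted p = 1.1e-08) or inosine replicate 2 (4.5e-06) and upward without glucose replicate 2 or inosine replicate 1 (0.014 for each). The count of genes went from 2 to 4 without glucose replicate 1 or 2 or inosine replicate 1 or 2, to 7 without inosine replicate 3, and to 1 without glucose replicate 3 or without replicate 2 or 3 with hypoxanthine.

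Adding hypoxanthine to inosine was accompanied by a wide change in expression. Among the genes with the largest rises were the chemokine genes Ccl5, from 9.7 ± 1.4 to 76.8 ± 6.96 FPKM, and Ccl1, from 9.72 ± 7.45 to 129 ± 3.94 FPKM (SD, n = 3). The inhibitory receptor gene Lag3 rose from 22.5 ± 2.8 to 134 ± 16.7 FPKM, and the interferon-inducible Ifi27l2a from 44.1 ± 15 to 463 ± 63.9 FPKM (SD, n = 3). The largest falls included Lmna, which encodes nuclear lamins A and C, from 24.7 ± 2.66 to 2.12 ± 0.198 FPKM, and the cytokine gene Lta, lymphotoxin alpha, from 238 ± 60.8 to 52.7 ± 1.08 FPKM (SD, n = 3). Gzmb was lower by 2.17 times, at 2585 ± 42.4 against 5610 ± 88 FPKM (SD, n = 3). limma called 4382 of 20618 genes (21.3%), 2404 higher and 1978 lower with hypoxanthine. Of these, 273 had a log2 difference of at least 1 in size, and 1114 had a mean under 1 FPKM. The count went to 2757 without replicate 3 of the hypoxanthine group, and 6707 genes had an unadjusted p under 0.05.

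The 8 largest rises were in Ccl1 (log2 difference 3.89, adjusted p = 0.015), Ifi27l2a (3.41, adjusted p = 0.00018), Ifi211 (2.93, adjusted p = 3.9e-06), the folate receptor family gene Izumo1r (2.91, adjusted p = 0.00044), Ccl5 (2.87, adjusted p = 3.5e-05), Nrgn (2.83, adjusted p = 0.00038), the thymic serine protease gene Prss16 (2.70, adjusted p = 1.3e-05) and Lag3 (2.52, adjusted p = 1.3e-05). The 8 largest falls were in Lmna (log2 difference -3.04, adjusted p = 4.4e-06), the TGF-beta family receptor gene Acvrl1 (-2.77, adjusted p = 1.3e-05), Gzmg (-2.50, adjusted p = 5.6e-06), Tnfrsf8, which encodes CD30 (-2.41, adjusted p = 4.4e-06), Pilrb1 (-2.32, adjusted p = 1.2e-05), Lta (-2.12, adjusted p = 0.00014), the annexin gene Anxa1 (-2.10, adjusted p = 1.4e-05) and Gzmd (-2.09, adjusted p = 3e-05). These differences are on the log2(FPKM + 1) scale, which understates the change of low genes. On the FPKM scale Acvrl1 was 22.6 times lower and Lmna 11.6 times lower. Without replicate 3 of the hypoxanthine group Ccl1 no longer passed (log2 difference 3.87, adjusted p = 0.053), nor without the 2 libraries of highest mitochondrial share, a choice made after seeing the data (3.27, adjusted p = 0.11; range over all alternatives 0.0028 to 0.11), and its inosine level had an SD close to its mean. Ifi211, Gzmd, Gzmg and Pilrb1 belong to families of near-identical copies between which reads can be split, so their single values are uncertain. On mm10, Lmna lies on chromosome 3 from 88481148 to 88509932, Lag3 on chromosome 6 from 124904359 to 124912434, Lta on chromosome 17 from 35203165 to 35205578 and Gzmb on chromosome 14 from 56258836 to 56262334.

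**Figure D1:**
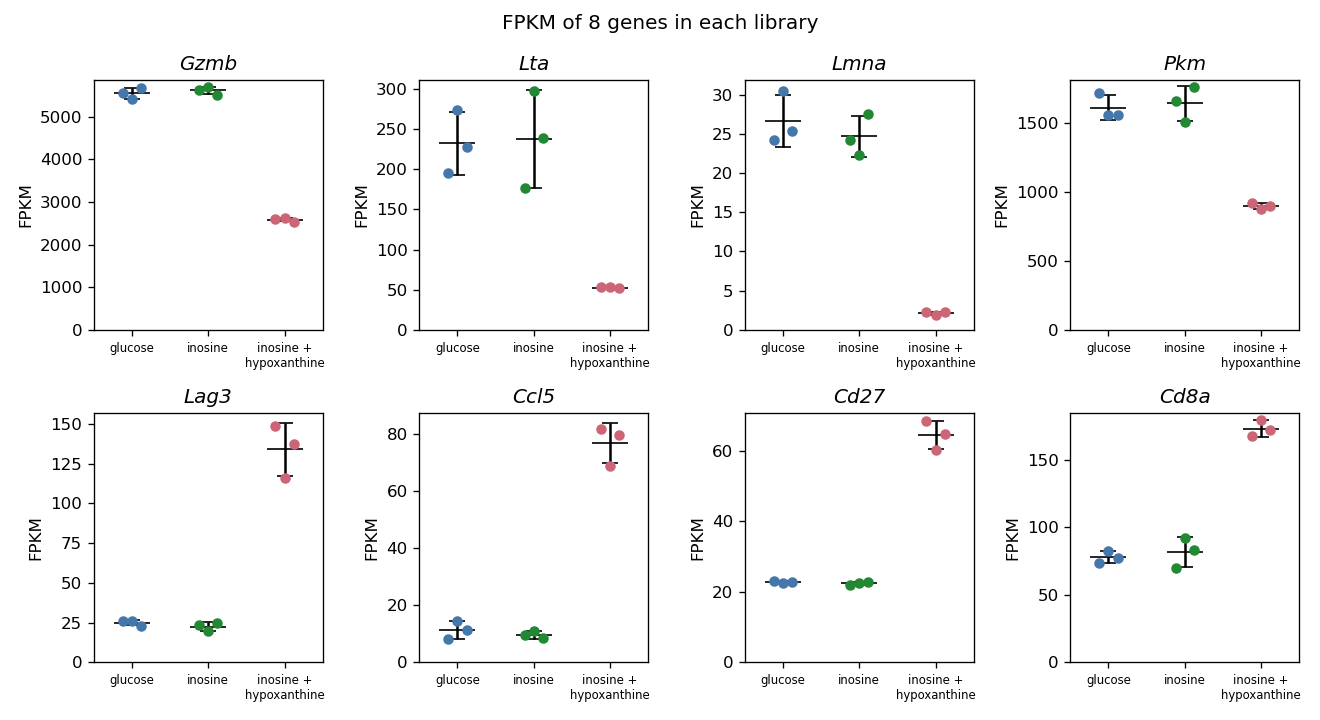
FPKM of 8 genes on a linear axis in each of the 9 libraries, by medium; points are libraries, the horizontal mark is the mean of 3 libraries and the bar its SD. Gzmb, Lta, Lmna and Pkm were lower with hypoxanthine than with inosine, and Lag3, Ccl5, Cd27 and Cd8a higher.

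Genes of T cell effector function went in both directions with hypoxanthine. Of 36 genes of the effector and cytotoxicity list, 13 fell, 9 rose and 14 did not pass, and 15 fell and 9 rose when adjusted over the list alone. Of the 8 granzyme genes of the list, 7 fell and Gzmk did not pass (limma adjusted p = 0.11). Among those that fell were Gzmc from 1576 ± 242 to 677 ± 38.5 FPKM, whose reads can be shared with its copies, and the transcriptional regulator gene Id2 from 157 ± 2.57 to 79.4 ± 1.2 FPKM (SD, n = 3). Tnf fell by 0.56 on the log2 scale (limma adjusted p = 0.0092), while Ifng had a difference of 0.26 ± 0.29 (standard error, adjusted p = 0.59). Prf1 fell by 0.86 on the log2 scale (adjusted p = 0.02). It did not pass without inosine replicate 1 (adjusted p = 0.056), without inosine replicate 3 (0.071), or without replicate 2 (0.07) or replicate 3 (0.065) of the hypoxanthine group, in a range over its alternatives of 0.0014 to 0.071. Ccl5 was among the 9 genes that rose. Camera placed the effector list downward at an adjusted p of 0.04997, and at an adjusted p of 0.349 with an estimated correlation. Its adjusted p was 0.067 under median-of-ratios scaling and 0.088, 0.077 and 0.061 without glucose replicates 1, 2 and 3, 0.065 without inosine replicate 3 or replicate 3 of the hypoxanthine group, and 0.05 (just over the threshold) without its replicate 1. It was 0.033 without inosine replicate 2, the lowest of the 9.

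The naive and memory list passed camera upward with hypoxanthine. Of its 26 genes, 13 rose, 2 fell and 11 did not pass, and 15 rose and 2 fell when adjusted over the list alone (camera adjusted p = 2.87e-06, and adjusted p = 0.0817 with an estimated correlation). The costimulatory receptor gene Cd27 rose from 22.4 ± 0.481 to 64.4 ± 4.06 FPKM and the transcription factor gene Bach2 from 2.23 ± 0.419 to 8.31 ± 0.65 FPKM (SD, n = 3). Satb1, at 37.2 ± 5.2 and 47.4 ± 4.12 FPKM, did not pass (SD, n = 3, adjusted p = 0.07), though it did without inosine replicate 1 (0.048) and with the mean FPKM filter (0.027). Of the 28 genes of the inhibitory receptor and exhaustion list, 14 rose, 7 fell and 7 did not pass, and 15 rose and 9 fell when adjusted over the list alone (camera adjusted p = 0.04997 upward, and adjusted p = 0.422 with an estimated correlation). Lag3 and the inhibitory receptor gene Tigit, from 33 ± 3.71 to 87.4 ± 8.11 FPKM, were among the risers, and Ctla4 stood at 98.4 ± 36.9 and 99.1 ± 7.76 FPKM (SD, n = 3, adjusted p = 0.92). Among the 7 that fell were the inhibitory receptor gene Havcr2 (log2 difference -0.84) and the ectonucleotidase gene Entpd1 (-0.92), both named after their values were seen. The call of this list was lost without any 1 of 8 libraries, at adjusted p from 0.052 without replicate 3 of the hypoxanthine group to 0.084 without glucose replicate 1, and it held without inosine replicate 1 (adjusted p = 0.036). Of the T cell receptor activation list of 33 genes, 18 rose, 4 fell and 11 did not pass, and 20 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.000896, and adjusted p = 0.221 with an estimated correlation). Its member Spry1, a feedback regulator of receptor signalling, rose from 1.93 ± 0.394 to 9.31 ± 1.27 FPKM, and Il2rb, the interleukin 2 receptor beta chain gene, fell from 332 ± 50.5 to 215 ± 16.3 FPKM (SD, n = 3). Of 14 T cell identity genes, 9 rose, 2 fell and 3 did not pass, with the same 9 and 2 adjusted over the list alone (camera adjusted p = 0.0119, and adjusted p = 0.221 with an estimated correlation). Cd8a rose from 81.5 ± 11.2 to 173 ± 6.02 FPKM and Cd3e from 82.8 ± 3.55 to 164 ± 12.3 FPKM (SD, n = 3). This call was lost without inosine replicate 1 (adjusted p = 0.076).

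The lists of MYC targets, of the integrated, endoplasmic reticulum and heat shock stress responses and of serine metabolism passed camera downward with hypoxanthine, with part of the genes of each not passing. Of 50 genes of the MYC target and ribosome biogenesis list, 37 fell, 1 rose and 12 did not pass, and 40 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.51e-18, and adjusted p = 0.0817 with an estimated correlation). The nucleolar protein gene Npm1 fell from 1828 ± 99.7 to 1239 ± 99.2 FPKM and the ribosome assembly gene Rrp12 from 19.6 ± 1.71 to 10.7 ± 0.803 FPKM (SD, n = 3). The gene that rose was Myc itself, named here after its values were seen, from 62.7 ± 12.4 to 105 ± 15 FPKM (SD, n = 3, adjusted p = 0.00956). Of the 41 genes of the integrated stress response list, which the transcription factor ATF4 drives, 26 fell, 1 rose and 14 did not pass, and 28 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.00e-11, and adjusted p = 0.29 with an estimated correlation). Atf4 fell from 217 ± 38.8 to 109 ± 5.03 FPKM, the threonyl-tRNA synthetase gene Tars from 66.6 ± 2.6 to 36.9 ± 1.31 FPKM and the stress gene Nupr1 from 10.2 ± 1.5 to 2.45 ± 0.171 FPKM (SD, n = 3). In the serine and one-carbon list of 25 genes, 11 fell, 1 rose and 13 did not pass, and 15 fell and 1 rose when adjusted over the list alone (camera adjusted p = 7.40e-06, and adjusted p = 0.161 with an estimated correlation). Phgdh, the entry enzyme of serine synthesis, fell from 224 ± 18.3 to 154 ± 4.51 FPKM (SD, n = 3). The endoplasmic reticulum stress list had 14 of 27 genes lower, 1 higher and 12 that did not pass, and 16 lower and 2 higher when adjusted over the list alone (camera adjusted p = 2.87e-06, and adjusted p = 0.116 with an estimated correlation). Its chaperone gene Hsp90b1 fell from 428 ± 12.7 to 258 ± 8.57 FPKM (SD, n = 3). In the heat shock list of 19 genes, 9 fell and 10 did not pass, and 9 fell when adjusted over the list alone (camera adjusted p = 0.00129, and adjusted p = 0.149 with an estimated correlation).

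Of 6 lists of energy and lipid metabolism described here, 5 passed camera downward with hypoxanthine, and fatty acid oxidation did not pass. Of 25 glycolysis genes, 9 fell and 16 did not pass, and 9 fell when adjusted over the list alone (camera adjusted p = 9.29e-05, and adjusted p = 0.366 with an estimated correlation). Pkm, the pyruvate kinase gene, fell from 1642 ± 125 to 900 ± 21.6 FPKM, Eno1 from 2340 ± 143 to 1240 ± 55.5 FPKM and Gapdh from 2687 ± 169 to 1637 ± 75.1 FPKM (SD, n = 3). Of 31 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 14 fell, 2 rose and 15 did not pass, and 19 fell and 2 rose when adjusted over the list alone (camera adjusted p = 8.74e-07, and adjusted p = 0.0817 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 15 lower of 76 and 61 that did not pass, and 15 lower when adjusted over the list alone (camera adjusted p = 4.04e-06, and adjusted p = 0.478 with an estimated correlation). This list did not pass fry (adjusted p = 0.0548). Atp5b fell from 743 ± 46.7 to 566 ± 25.7 FPKM (SD, n = 3). In cholesterol synthesis 16 of 26 genes fell and 10 did not pass, and 17 fell when adjusted over the list alone (camera adjusted p = 1.01e-08, and adjusted p = 0.161 with an estimated correlation). Lss, which closes the sterol ring, fell from 16.1 ± 2 to 7.28 ± 0.389 FPKM, and Srebf2, the transcription factor gene of the pathway, stood at 51.4 ± 12 and 56.4 ± 8.66 FPKM (SD, n = 3, adjusted p = 0.61). In fatty acid synthesis 8 of 20 genes fell, 1 rose and 11 did not pass, and 9 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00375, and adjusted p = 0.387 with an estimated correlation). The desaturase gene Scd1 fell from 19.4 ± 4.5 to 5.94 ± 0.614 FPKM (SD, n = 3). In fatty acid oxidation 3 of 26 genes rose, 4 fell and 19 did not pass, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.609, and adjusted p = 0.672 with an estimated correlation).

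The list of genes that handle inosine and hypoxanthine did not pass camera. Of the 30 genes of the inosine and purine salvage list, 9 rose, 5 fell and 16 did not pass, with 9 and 5 adjusted over the list alone (camera adjusted p = 0.913, and adjusted p = 0.948 with an estimated correlation). Pnp fell by 0.47 on the log2 scale, from 26.7 ± 3.17 to 18.9 ± 1.3 FPKM, and Pgm2, whose product acts on ribose 1-phosphate, from 9.51 ± 0.565 to 7.28 ± 0.373 FPKM (SD, n = 3, limma adjusted p = 0.0066 and 0.0084). Xdh, which oxidizes hypoxanthine, rose from 8.03 ± 0.204 to 14.9 ± 1.54 FPKM, and the nucleoside transporter gene Slc29a1 from 35.1 ± 2.6 to 49.6 ± 1.31 FPKM (SD, n = 3, adjusted p = 0.0033 and 0.0015). Hprt, which salvages hypoxanthine, stood at 138 ± 12.5 and 116 ± 11.4 FPKM and did not pass (SD, n = 3, adjusted p = 0.1), though it did without replicate 2 of the hypoxanthine group (0.044). The adenosine deaminase gene Ada had a log2 difference of 0 ± 0.08, Slc2a1 one of -0.21 ± 0.21, Txnip -0.74 ± 0.41 and Carm1 -0.05 ± 0.16 (standard error, adjusted p = 1, 0.56, 0.26 and 0.87). The adenosine receptor gene Adora2a rose by 0.71 ± 0.21 (standard error, adjusted p = 0.04). It no longer passed without glucose replicate 3 (adjusted p = 0.066), inosine replicate 2 (0.082) or replicate 3 (0.081), or replicate 1 (0.12), 2 (0.074) or 3 (0.12) of the hypoxanthine group, nor under median-of-ratios scaling (0.052), with the 6 libraries compared (0.063) or without the 2 libraries of highest mitochondrial share (0.12), in a range over its alternatives of 0.0074 to 0.12. Of 16 genes of purine synthesis from small precursors, 6 fell and 10 did not pass, and 9 fell when adjusted over the list alone (camera adjusted p = 0.00673, and adjusted p = 0.116 with an estimated correlation). In the pyrimidine and deoxynucleotide list 7 of 20 genes fell, 1 rose and 12 did not pass, and 7 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.000442, and adjusted p = 0.0817 with an estimated correlation). The uridine phosphorylase gene Upp1 fell from 40.2 ± 13.7 to 8.82 ± 0.606 FPKM (SD, n = 3).

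Of the interferon-stimulated and ribosomal protein lists, part of the genes rose with hypoxanthine and most did not pass. Of 60 interferon-stimulated genes, 16 rose and 44 did not pass, and 18 rose when adjusted over the list alone (camera adjusted p = 3.18e-06, and adjusted p = 0.584 with an estimated correlation). This list did not pass fry (adjusted p = 0.12). Ifi27l2a was the most significant, and Psmb8 stood at 202 ± 10 and 208 ± 1.43 FPKM (SD, n = 3, adjusted p = 0.71). Of 82 ribosomal protein genes, 18 rose, 1 fell and 63 did not pass, and 21 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.87e-06, and adjusted p = 0.584 with an estimated correlation). It did not pass fry either (adjusted p = 0.0698). Rpl17 rose from 1305 ± 200 to 1960 ± 215 FPKM (SD, n = 3). Ribosomal protein genes took 28.7 to 32.1% of the FPKM in the libraries with hypoxanthine and 23.8 to 27.1% in the other 6. In the adenosine and cyclic AMP list 10 of 24 genes rose, 2 fell and 12 did not pass, and 12 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.00435, and adjusted p = 0.473 with an estimated correlation). Nr4a1, an immediate early nuclear receptor gene, rose from 5.7 ± 1.19 to 17.7 ± 1.8 FPKM, and the receptor gene Adora2b fell from 7.41 ± 0.381 to 3.49 ± 0.177 FPKM (SD, n = 3). Proliferation lists did not pass. In the S phase list 5 of 60 genes rose and 6 fell, with 4 and 6 adjusted over the list alone (camera adjusted p = 0.346, and adjusted p = 0.89 with an estimated correlation). In the G2 and mitosis list 8 of 63 rose and 3 fell, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.492, and adjusted p = 0.89 with an estimated correlation). The S phase list passed without inosine replicate 1, downward (adjusted p = 0.0045). Mki67 stood at 50.3 ± 2.71 and 57.3 ± 2.99 FPKM (SD, n = 3, adjusted p = 0.38).

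The remaining lists that passed with hypoxanthine against inosine, of 25 in all (8 upward and 17 downward, 0 with an estimated correlation, where 13 had an unadjusted p under 0.05, and 26 with fry), were those of smaller pathways. In the arginine methylation list, named for Carm1, 4 of 10 genes fell and 6 did not pass, with 4 adjusted over the list alone (camera adjusted p = 0.00812, and adjusted p = 0.157 with an estimated correlation). The methyltransferase genes Prmt5, from 106 ± 3.57 to 60.8 ± 1.27 FPKM, and Prmt1, from 238 ± 5.47 to 165 ± 3.69 FPKM (SD, n = 3), were among them (limma adjusted p = 6.7e-05 and 0.0011), while Carm1 did not pass. In the p53 target list 12 of 31 fell, 3 rose and 16 did not pass, with 12 and 3 adjusted over the list alone (camera adjusted p = 0.000706, and adjusted p = 0.161 with an estimated correlation), and the cell cycle inhibitor gene Cdkn1a fell by 1.24 on the log2 scale. In the NRF2 antioxidant list 11 of 30 fell, 3 rose and 16 did not pass, with 13 and 5 adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.139 with an estimated correlation). In the pentose phosphate list 7 of 18 fell, 1 rose and 10 did not pass, with 8 and 2 adjusted over the list alone (camera adjusted p = 0.00415, and adjusted p = 0.116 with an estimated correlation). In the lysosome and autophagy list 14 of 44 rose, 2 fell and 28 did not pass, with 19 and 3 adjusted over the list alone (camera adjusted p = 0.0167, and adjusted p = 0.32 with an estimated correlation). That call was lost without inosine replicate 2 (adjusted p = 0.051) or replicate 1 of the hypoxanthine group (0.052).

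**Figure D2:**
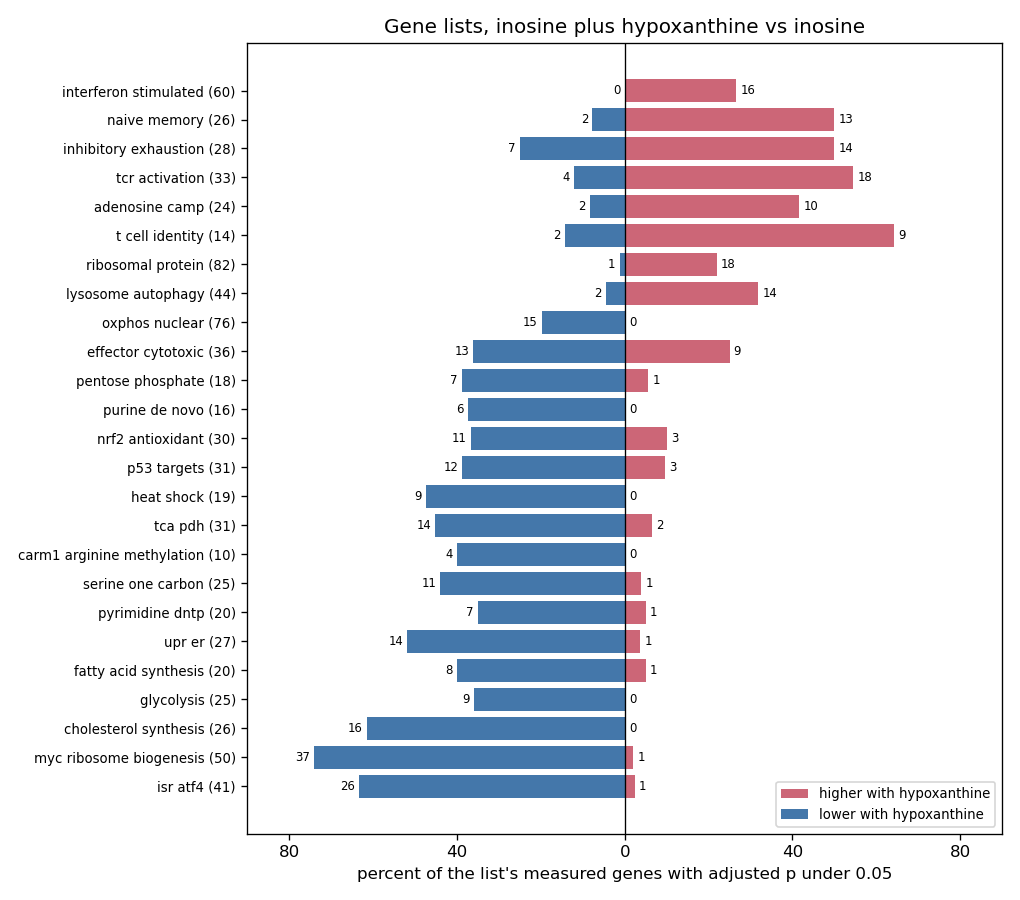
Gene lists that passed camera with a preset correlation in the comparison of inosine plus hypoxanthine with inosine, ordered by mean log2 difference, with the number of measured genes in brackets. Bars give the percentage of each list that passed limma, to the right for higher and to the left for lower with hypoxanthine, and the numbers beside them are gene counts; 37 of 50 genes of the MYC and ribosome biogenesis list were lower, and none of the 25 lists passed with an estimated correlation.

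Most markers of other cell types had low values in all 3 media. The median over 12 B cell markers was 0.0287 FPKM in inosine and 0.0255 FPKM with hypoxanthine, over 16 myeloid markers 0.0248 and 0.0183 FPKM, over 7 erythroid markers 0.0254 and 0.0147 FPKM over 12 stroma and epithelium markers 0.0438 and 0.0493 FPKM and over 10 natural killer and gamma delta T cell markers 0.0225 and 0.122 FPKM. It was 0.302 and 0.254 FPKM over 10 dendritic cell markers and 1.0 and 1.11 FPKM over 6 markers of CD4 and regulatory T cells. Of these 6, the neuropilin gene Nrp1 rose from 1.9 ± 0.0485 to 4.54 ± 0.583 FPKM (SD, n = 3, limma adjusted p = 0.00023) and the other 5 did not pass. The highest single marker was Bst2 of the dendritic cell list, an interferon-inducible gene named here after its values were seen, at 93.8 ± 14.4 and 110 ± 1.83 FPKM (SD, n = 3, limma adjusted p = 0.213). Among the myeloid markers Fcer1g fell from 9.19 ± 1.36 to 3.5 ± 0.514 FPKM, and among the dendritic cell markers Cd74 rose from 3.94 ± 0.689 to 7.27 ± 1.37 FPKM (SD, n = 3, limma adjusted p = 0.0048 and 0.0096). None of the 7 lists of markers of other cell types passed camera with hypoxanthine against inosine (lowest adjusted p = 0.0779, for natural killer and gamma delta T cells), but that list passed without inosine replicate 1 (adjusted p = 0.027, upward) and against glucose (adjusted p = 0.0333, and adjusted p = 0.16 with an estimated correlation). Against glucose 3 of its 10 genes rose and 7 did not pass, with 3 higher and 1 lower adjusted over the list alone, and the call was lost without glucose replicate 2 (adjusted p = 0.066).

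Against glucose, cells with inosine plus hypoxanthine showed much the same leading genes. Lmna fell by 3.14 on the log2 scale, from 26.7 ± 3.31 to 2.12 ± 0.198 FPKM, and Gzmb by 1.1, from 5549 ± 127 to 2585 ± 42.4 FPKM (SD, n = 3, limma adjusted p = 3.2e-06 and 2.3e-05). The chemokine gene Xcl1 rose from 171 ± 118 to 833 ± 22.7 FPKM and Ccl5 from 11.4 ± 3.22 to 76.8 ± 6.96 FPKM (SD, n = 3, adjusted p = 0.012 and 4.6e-05). The 8 largest rises were in Ccl1 (log2 difference 4.19), Ifi27l2a (3.41), Ifi211 (2.95), Izumo1r (2.83), Nrgn (2.80), Prss16 (2.73), Ccl5 (2.68) and Xcl1 (2.55), and the 8 largest falls in Lmna (-3.14), Acvrl1 (-2.83), Tnfrsf8 (-2.53), Gzmg (-2.44), Pilrb1 (-2.26), Lta (-2.11), Gzmd (-1.99) and Upp1 (-1.97). limma called 4192 of 20618 genes, 2224 higher and 1968 lower, and 275 of them had a log2 difference of at least 1 in size. Without replicate 3 of the hypoxanthine group the count was 2677. Of the 43 lists, 24 passed camera, 8 upward and 16 downward, and 0 passed with an estimated correlation (smallest adjusted p = 0.102, 12 with an unadjusted p under 0.05), while 26 passed fry. In the MYC target and ribosome biogenesis list 38 of 50 genes fell, 1 rose and 11 did not pass, with 43 and 1 adjusted over the list alone (camera adjusted p = 2.24e-18, and adjusted p = 0.102 with an estimated correlation). In the integrated stress response list 28 of 41 fell and 13 did not pass, with 30 lower and 1 higher adjusted over the list alone (camera adjusted p = 5.61e-12, and adjusted p = 0.282 with an estimated correlation). In glycolysis 9 of 25 fell and 16 did not pass, with 10 adjusted over the list alone (camera adjusted p = 3.34e-05, and adjusted p = 0.362 with an estimated correlation). In the naive and memory list 10 of 26 rose, 2 fell and 14 did not pass, with 13 and 2 adjusted over the list alone (camera adjusted p = 3.34e-05, and adjusted p = 0.114 with an estimated correlation). The effector list, with 8 genes higher, 14 lower and 14 that did not pass of 36, and 9 and 16 adjusted over the list alone, did not pass camera (adjusted p = 0.0776, and adjusted p = 0.386 with an estimated correlation). It passed, downward, without glucose replicate 2 (adjusted p = 0.028) and without replicate 2 of the hypoxanthine group (0.05, just under the threshold).

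Of the fixed genes in the comparison with glucose, Slc29a1 rose by 0.50 and Xdh by 0.67 on the log2 scale, and Tnf fell by 0.50 (limma adjusted p = 0.0015, 0.0086 and 0.016). Tnf did not pass without glucose replicate 2 (adjusted p = 0.057) or without replicate 1 or 3 of the hypoxanthine group (0.054 for each). Prf1 fell by 0.87 (adjusted p = 0.02), and did not pass without glucose replicate 1 (0.07) or 3 (0.056) or replicate 2 (0.073) or 3 (0.064) of the hypoxanthine group. Pnp fell by 0.33 (adjusted p = 0.031). It did not pass without glucose replicate 1 (0.07), 2 (0.069) or 3 (0.099), inosine replicate 3 (0.05), or replicate 1 (0.095) or 3 (0.11) of the hypoxanthine group, nor under upper-quartile scaling (0.11), in a range over its alternatives of 0.013 to 0.11. Values that did not pass were those of Hprt (log2 difference -0.17), Pgm2 (-0.22), Ada (0.04), Slc2a1 (-0.29), Txnip (-0.68), Ifng (0.48), Adora2a (0.67) and Carm1 (-0.23), with adjusted p of 0.26, 0.056, 0.78, 0.41, 0.31, 0.3, 0.052 and 0.38. Adora2a passed without glucose replicate 1 (0.031) or inosine replicate 1 (0.039) or 2 (0.015), and Pgm2 and Adora2a passed with the mean FPKM filter (0.043 and 0.021).

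The comparisons of hypoxanthine with inosine and with glucose shared most of their genes. Of the genes called higher, 1931 were shared, where independent lists of the same sizes would share 259.3, and of those called lower, 1581 were shared against 188.8. None was called in opposite directions. Both comparisons use the libraries with hypoxanthine, so their lists are not independent. Simulated unchanged groups shared at most 1 call in 50 simulations. With no gene changed almost none is called, so this does not measure how much of the overlap comes from the shared libraries. Across all genes the differences had the same sign for 79.5% of genes against 66.6% in the same 50 simulations. Any gene at 0 in all libraries counts as the same sign in the data, but not in these simulations. The 2 shares are therefore not fully alike. With 3 libraries the shared group could not be split into parts of 2, so part of the excess may come from the shared libraries. The covariance of the differences was 0.0841, against 0.00267 in the simulations (p = 0.001 by simulation for the covariance, the smallest it can give; Pearson r = 0.96 across genes). Genes are not independent replicates.

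The test among all 3 media called 3978 genes with limma's F statistic. The most significant with higher levels under hypoxanthine were Ifi211, Ifi205, from 0.555 ± 0.0371 FPKM in inosine to 5.89 ± 0.594 FPKM with hypoxanthine, and the tetraspanin gene Tspan32, from 4.21 ± 0.154 to 14 ± 0.386 FPKM (SD, n = 3). Those with lower levels were Tnfrsf8, Lmna and Gzmg. Ifi205 belongs to the family of near-identical copies that holds Ifi211. The count went to 2427 without replicate 1 and to 2105 without replicate 3 of the hypoxanthine group. To ask whether hypoxanthine moved genes back toward their level in glucose, the difference of inosine from glucose was set against that of hypoxanthine from inosine. They were set against simulated unchanged groups, which share the inosine libraries with opposite signs. Across 20618 genes the covariance was -0.00371 against -0.0058 (-0.0134 to -0.0014), an excess of 0.00209 (p = 0.6 by simulation, for the covariance) with r = -0.16, a value that the spread of the second difference (variance 0.0878 against 0.00617) pulls toward 0 whatever the relation. Without inosine replicate 3 the excess covariance was 0.00874, and none of 1000 simulated covariances lay as far from their mean. In that fit the rotation can only turn the sign of the inosine deviations. The simulated spread is therefore too narrow, and no conclusion is drawn from it. The same comparison for the differences of both media from glucose gave a covariance of 0.00246 against 0.00403 (r = 0.11, p = 0.62 by simulation, for the covariance).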

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

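Chosen after seeing the data were median-of-ratios scaling with the mean FPKM filter, voom with the read filter, the list test with a mean FPKM of at least 1, and the fit without the 2 libraries of highest mitochondrial share. For inosine against glucose the count of 2 genes became 1 with upper-quartile scaling, 1 with the replicate block and 1 without the 2 libraries of highest mitochondrial share. It became 0 with a mean FPKM of at least 1, with 10 recovered reads in 3 libraries and mean CPM of at least 1, with limma voom on recovered reads, with median-of-ratios scaling and the mean FPKM filter, with voom and the read filter, with a log2 fold change of at least 1, and with only the 6 libraries compared. The filters remove both called genes, which are near 0 FPKM; otherwise the cause was not tested. With a log2 fold change of at least 1, the counts with hypoxanthine were 273 against inosine and 275 against glucose, by construction. Leaving out 1 library gave 1 to 7 genes for inosine against glucose, 2757 to 4487 for hypoxanthine against inosine, 2677 to 4879 against glucose and 2105 to 4285 among the 3 media; the cause was not tested, but such fits hold fewer libraries. Lists passing for inosine against glucose were 0 with an estimated correlation, 0 with fry, 2 with a mean FPKM of at least 1 and 1 to 8 with 1 library left out, and with an estimated correlation 0 passed with hypoxanthine against inosine and 0 against glucose (13 and 12 with an unadjusted p under 0.05; 25 and 24 with the preset correlation and 26 in both with fry). For inosine against glucose 0 lists had an unadjusted p under 0.05 with an estimated correlation or fry. The excess covariance of 0.00209 ranged from -0.00217 to 0.00874 with 1 library left out. For named genes, 10554 of 10849 values under alternatives kept their side of the threshold, 157 no longer passed and 138 came to pass. Among those that passed, 0 turned direction. Values that did not pass can turn when a library is left out. One such gene for inosine against glucose was Txnip, at 23.8, 71 and 48.5 FPKM in glucose replicates 1, 2 and 3 and 26.6, 71.4 and 49 FPKM in inosine. The labels give no shared origin for equal replicate numbers, so the samples were not treated as paired: 4 of 9 pairs with the same number had a correlation over 0.1 (-0.27 to 0.64), though 6 of 9 libraries correlated best with their own number. For replicates 1, 2 and 3 the correlations were 0.4, 0.26 and -0.27 between glucose and inosine, 0.41, 0.64 and 0.02 between inosine and hypoxanthine, and 0.08, -0.2 and -0.06 between glucose and hypoxanthine. On the second principal component the order was replicate 1, then 3, then 2 in each medium. The values were 10.2, -0.4 and -1.2 in glucose, 11.1, 0.5 and -19.9 in inosine, and 5.3, 2.1 and -7.7 with hypoxanthine. With the correlations of replicates 1 and 2, this points to variation shared by number between glucose and inosine. The correlation of replicate 3 (-0.27) went the other way. Shared variation would widen the errors of the unpaired test, so small differences between inosine and glucose can be missed. With the replicate block, 4396 genes were called with hypoxanthine against inosine, 4251 against glucose and 3868 among the 3 media. A DESeq2 test had been set out and was not run: the deposited values per library are FPKM, though the recovered reads would have allowed it. A filter of at least 1 count equals no filter here. Against the authors' adjusted p under 0.05, 0 of 1, 3766 of 4541 and 3715 of 5259 genes were also called here for inosine against glucose, hypoxanthine against inosine and hypoxanthine against glucose. The authors' 1 gene for inosine against glucose, named after its values were seen, was Sp6 (their log2 fold change -4.97, lower in inosine).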

Other observations

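Among tests in this part, those of KEGG maps, of other cell types and of the granzyme genes were chosen after the result was seen. Of 277 KEGG maps, 46 passed camera with hypoxanthine against inosine, and 0 passed with an estimated correlation (33 with an unadjusted p under 0.05). Ribosome biogenesis had 38 of 74 genes lower and 0 higher (camera adjusted p = 9.6e-13, and adjusted p = 0.18 with an estimated correlation). Aminoacyl-tRNA biosynthesis had 21 of 44 lower and 1 higher (1.7e-07, and 0.12), and the proteasome 19 of 47 lower and 2 higher (2.8e-06, and 0.51). The asparaginyl-tRNA synthetase gene Nars, named after its values were seen, fell from 126 ± 10.1 to 65.5 ± 0.568 FPKM (SD, n = 3, limma adjusted p = 0.000284).

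Of 20618 genes, 4382 differed when hypoxanthine was added to inosine. After thinning to equal depth 94.3% of the limma voom calls were kept (4655 to 4548 calls), which argues against depth. After removing trends with GC content and gene length 94.2% of the calls were kept among 9638 genes, and the total rose from 3879 to 4621 calls. This argues against those trends as the whole cause. The highest median of the B cell, myeloid, erythroid and stroma lists with hypoxanthine was 0.0493 FPKM, which argues against RNA of those 4 kinds of cells. For types outside this test, single markers were low with hypoxanthine. They were Cd4 (0.0213 FPKM), Foxp3 (0.0364), the natural killer genes Ncr1 (0.0117) and Klrb1c (0.169) and the dendritic cell genes Flt3 (0.01) and Itgax (0.0542). Other members of their lists were higher, such as Nrp1 (4.54 FPKM), Klre1 (1.68) and H2-Ab1 (6.07). The natural killer and gamma delta T cell list also passed camera against glucose, so RNA of these types is not excluded. An effect of the medium may remain, as a hypothesis, and a difference in handling between media that the labels do not record was not tested.

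Few genes differed between inosine and glucose. For 99.6% of 9947 genes the 95% interval of the log2 difference lay inside -1 to 1. The scale is log2(FPKM + 1), so for genes near 1 FPKM this bound is a change of more than 2 times. For genes well above 1 FPKM it argues against a spread too wide to show changes of 2 times. Smaller changes stay open, and so do changes of 2 times in low genes. The most genes called by another split of the 6 libraries was 5, which argues against a swap of libraries that hides a large difference between the media. A swap between media that do not differ would leave no trace in this test. The lowest chi-square per degree of freedom between a glucose and an inosine library was 12.84, for replicate 1 of each. For 2 sets of reads from 1 library it would be about 1, which argues against 1 library deposited under both. The value of 12.84 was lower than any pair within glucose (lowest 13.12) or inosine (lowest 19.27). These 2 libraries of equal number were thus closer than any 2 of the same medium among glucose and inosine. The real split called 2 genes with limma, 4 of 10 splits called as many, and the splits are too few for a share under 0.05.

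Of 10 granzyme genes, 7 were lower with hypoxanthine, and Gzmk, Gzmm and Gzmn did not pass (limma adjusted p = 0.11, 1 and 0.61). Summed over 10 genes, FPKM had a ratio of 0.437 (8046 ± 216 to 3512 ± 84.1, SD, n = 3). Gzmb, at 5610 FPKM in inosine, holds most of this sum. Without Gzmb the sum was 2281 to 2664 FPKM in the inosine libraries and 880 to 954 FPKM in those with hypoxanthine. Gzmk, Gzmm and Gzmn stood at 0.658, 0.481 and 0.0189 FPKM in inosine, and none of the 10 genes was higher with hypoxanthine. Both sums therefore had to fall and are no separate test. A move of reads among these genes would raise some of them. The lack of any rise argues against such a move as the whole cause, while reads lost to other genes were not tested. Under 2 other scalings the median log2 difference nearest to 0 was -1.41, but these shift the media by at most 0.037 on the log2 scale and could not have changed the outcome. A scaling factor moves all genes of a library alike, so it cannot give a fall relative to other genes (median -1.38 against 0.002 over all genes), while the amount per cell cannot be read from FPKM and stays open. A lower level of the 7 transcripts with hypoxanthine may remain, as a hypothesis found and tested on the same data.

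Among the 3 media the real grouping called 3978 genes, and 2 of 100 splits, the real one among them, called as many, a share under 0.05. This argues against a random allotment of libraries to media, if the libraries are independent. The labels do not state that they are, so a chance difference between cultures is not excluded. The highest other split called 4640 genes and keeps the 3 libraries with hypoxanthine together, which points to those libraries as the structure of the samples. For the 2 comparisons with hypoxanthine the 10 splits of 6 libraries are too few for a share under 0.05: the real split called 4382 genes against inosine and 4192 against glucose, 1 of 10 splits each, and the highest other split called 2 in each.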
